A study of Mus musculus with 4 samples.

How the data were processed

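Transcript levels were measured by RNA sequencing in 4 libraries of primary squamous cell carcinomas of mice, 2 from control tumours and 2 from tumours in which Kdm4a had been knocked out in an inducible manner. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was selected on Dynabeads, and libraries were made with a stranded Kapa kit. Per the labels, the tumours were not cultured. Per the submitters' processing notes, TopHat and Cufflinks were used with the mouse genome build mm9; their versions, the gene annotation and the strand setting of the counting are not given in the sources used here.

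The authors deposited 1 table of 14159 genes and 4 value columns, each used here. The values were read as FPKM (fragments per kilobase of transcript and 1e6 mapped fragments) made by the authors with Cufflinks, although the deposited sheet is named for CPM (reads per 1e6 reads). The columns summed to between 592281 and 626719, the smallest value above 0 was 1.8e-05, and levels did not rise with transcript length in any library (rank correlation across 14031 genes from -0.085 to 0.013), which CPM values do. The test planned before the data were examined assumed CPM; the same test on the log scale was used for FPKM. The lowest mean of a gene over the 4 libraries was 0.25, so the authors appear to have filtered on that mean. The number of reads behind each value is unknown, whole reads could not be recovered from the low values, and no counting interval or detection limit is given. An exact 0 in such a table can be a failed estimate, so such genes are described as listed at 0.

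Both control columns carry the same name, so each is known to be a control library but not which; they are called control libraries a and b here. The knockout columns are named 1 and 2. Nothing in the labels says whether the libraries came from separate animals or tumours. The p-values therefore measure only the spread between these samples, which may be technical.

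Genes with at least 1 FPKM in at least 2 of the 4 libraries were tested, which kept 12046. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), knockout against control, with no covariate. The test was two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The residual degrees of freedom were 2 and the prior added 2.93. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values; SE is limma's moderated standard error. Ratios of group means are on the FPKM scale.

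Before the data were examined, 36 gene lists were written, covering interferon and antigen presentation, DNA replication and repair, squamous tumour biology, RNA quality and the cell types such a tumour could hold. The 32 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists. Each call was repeated with an estimated correlation, which here rests on 2 residual degrees of freedom, and with fry, which asks whether a list's genes move one way on balance and compares them with no other genes. The 4 lists not tested were mitochondrially encoded genes (0 members in the table), Schwann cell and nerve (4 tested members), erythrocyte (2) and mast cell (0 tested of 5 in the table).

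Genes were named by a rule also written beforehand: Kdm4a; the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 and no provisional symbol; the 2 members of each list with the smallest p, or 3 for the interferon, chemokine, replication and repair lists; and Cxcl9, Cxcl10, Cxcl11, Ccl5, Cd8a, Ifng, Bmi1, Krt5, Krt14, Trp63, Mki67 and Cdkn1a. Ifng is not among the genes analysed here. A few genes that this rule names are not reported here. Other genes are said to have been chosen after their values were seen.

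Transcript lengths (the longest annotated transcript) and genomic spans came from GENCODE M21 on GRCm38, matched by symbol or a unique older symbol for 99.1% of the genes. They are properties of the gene and not the models the authors used on mm9. Genes of families with near-identical members, among them Hspa1a and Hspa1b, class I H2 genes, histone genes, Ifna genes and salivary secretory genes, can share reads, and their single values are uncertain. Small RNAs encoded inside host genes can take reads of the host.

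The gene test was tested on simulated data made from the real genes, 2 libraries against 2 over 12046 genes. It recovered 5 of 50 genes changed by 0.5 on the log2 scale, 40 of 50 changed by 1, 48 of 50 changed by 2 and 49 of 50 changed by 3. Of 150 calls, 8 were false. The simulation changed only 50 genes of each size, whereas 63.9% of the real genes were called. Its genes varied independently, with spreads drawn from limma's own prior and no length trend. Its recovery and false calls therefore need not hold for the real data. In the list test, the 1 list that had been shifted was called and none of the 31 others was. The simulated genes varied independently and the lists were random genes, whereas estimated correlations in the real lists reached 0.95. The list simulation therefore does not test the preset correlation of 0.01.

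There were 17 alternatives planned and run: pseudocounts of 0.1, 0.5 and 5, no filter, a filter of 5 FPKM, median-ratio scaling, quantile normalization, eBayes without a trend, robust eBayes, each library left out in turn, an adjusted p of 0.1, a change of at least 1 on the log2 scale, the estimated correlation and fry. With 1 library left out, limma pools the spread and the lone library of a group is assumed to vary like the other group. After the data were seen, 2 were added: removal of the trend with transcript length and genomic span from each library (a loess fit with a span of 0.5), and the omission of genes with transcripts under 300 nt.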

Results

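RNA was sequenced from primary mouse squamous cell carcinomas, tumours of squamous epithelium, with and without an inducible knockout of Kdm4a, 2 libraries in each group. Kdm4a encodes a histone demethylase that acts on methylated lysines 9 and 36 of histone H3. The title of the series names tumour immunity, resistance to PD1 blockade and DNA replication stress as its subjects, and knockout against control is the comparison its labels give. FPKM values were analysed for 14159 genes, of which 12046 were tested. The depth of the libraries is unknown. On the log2(FPKM + 1) scale, the Pearson correlation across genes was 0.96 between the control libraries, 0.96 between the knockout libraries and 0.89 to 0.90 between libraries of different groups. Among 6844 genes with a mean of at least 10 FPKM, the median absolute log2 difference was 0.06 between the control libraries, 0.13 between the knockout libraries and 0.45 to 0.48 across groups.

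Kdm4a was lower in both knockout libraries. It stood at 29.6 and 27.7 FPKM in the control libraries and at 14.9 and 14.7 FPKM in the knockout libraries, a log2 fold change of -0.91 (SE 0.07, limma adjusted p = 0.00077). Transcript therefore remained at 0.517 times the control level. The gene lies on the minus strand of chromosome 4 from 118136957 to 118180043 in GRCm38, and the values do not show which exons the knockout removes. Of its relatives, chosen after their values were seen, Kdm4c was lower as well (15.0 ± 1.14 FPKM in control, 6.82 ± 0.24 in knockout, SD, n = 2; log2 fold change -1.03, adjusted p = 0.00101), and Kdm4b differed by 0.06 (adjusted p = 0.665; 0.28 with 0.049 after the trend with gene length was removed). Among 200 genes of like transcript length, 38 were as low as Kdm4a, and their median was -0.12.

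Expression differed between the groups across much of the transcriptome, with 3628 genes higher and 4073 lower in knockout, 63.9% of those tested. At an absolute log2 fold change of at least 1, 822 were higher and 1228 lower. Without control library a or b, 44.6% and 43.5% of the genes were called. The largest changes under the naming rule were mostly small RNA genes listed at 0 in 1 of the groups. Polyadenylated RNA was selected, and small RNAs encoded inside host genes can take reads of the host. The values of such genes therefore need not measure the small RNAs themselves. Mir6941, Snord49a, Mir1982 and Snord1b were listed at 0 in both control libraries, with knockout means of 547, 517, 235 and 185 FPKM. Snord47, Mir1902, Snora61, Mir5132, Mir6912 and Mir324 were listed at 0 in both knockout libraries, with control means of 307, 221, 199, 198, 103 and 52.0 FPKM. Mir1938 stood at 57.2 and 0 FPKM in the control libraries and 2380 and 2335 in knockout, and its call was lost without either knockout library (adjusted p = 0.0703 and 0.0719) and with robust eBayes (0.126). Its log2 fold change of 8.27 was 11.2 without control library a and 5.34 without b, and that of Mir5132 (-7.45) was -8.19 and -6.71.

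Applied after the values were seen to genes with transcripts of at least 500 nt, the same rule named secretory genes among the rises. Bpifa2, Smr3a, Pip, Chia1 and Amy1 encode secreted proteins found in saliva or gland secretions. Bpifa2 was listed at 1.27 and 19.9 FPKM in control and at 2831 and 619 in knockout (log2 fold change 7.59, SE 1.24, adjusted p = 0.00511). Leaving out 1 library moved that log2 fold change to between 5.98 (without control library a) and 9.19 (without b). Smr3a rose by 7.19, Pip by 5.99, Chia1 by 5.39 and Amy1 by 5.01, and all were lower in knockout library 2 than in library 1. Without knockout library 1 these were 5.99, 5.27, 4.04 and 4.21, and without library 2 they were 8.40, 6.72, 6.74 and 5.80. With robust eBayes the calls on Bpifa2, Smr3a and Chia1 were lost (adjusted p = 0.0733, 0.0643 and 0.0687). Eif3j2, whose reads may be shared with a near-identical gene, rose by 5.69 (5.09 without control library a and 6.30 without b). The falls were Mipol1 (-4.21), the small RNA host Snhg5 (-3.73), Thsd4 (-3.67), Pxdc1 (-3.56), Grip1 (-3.50) and the differentiation inhibitor Id4 (-3.26). Mipol1 fell from 41.4 ± 0.691 to 1.30 ± 0.0154 FPKM (SD, n = 2).

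**Figure D1:**
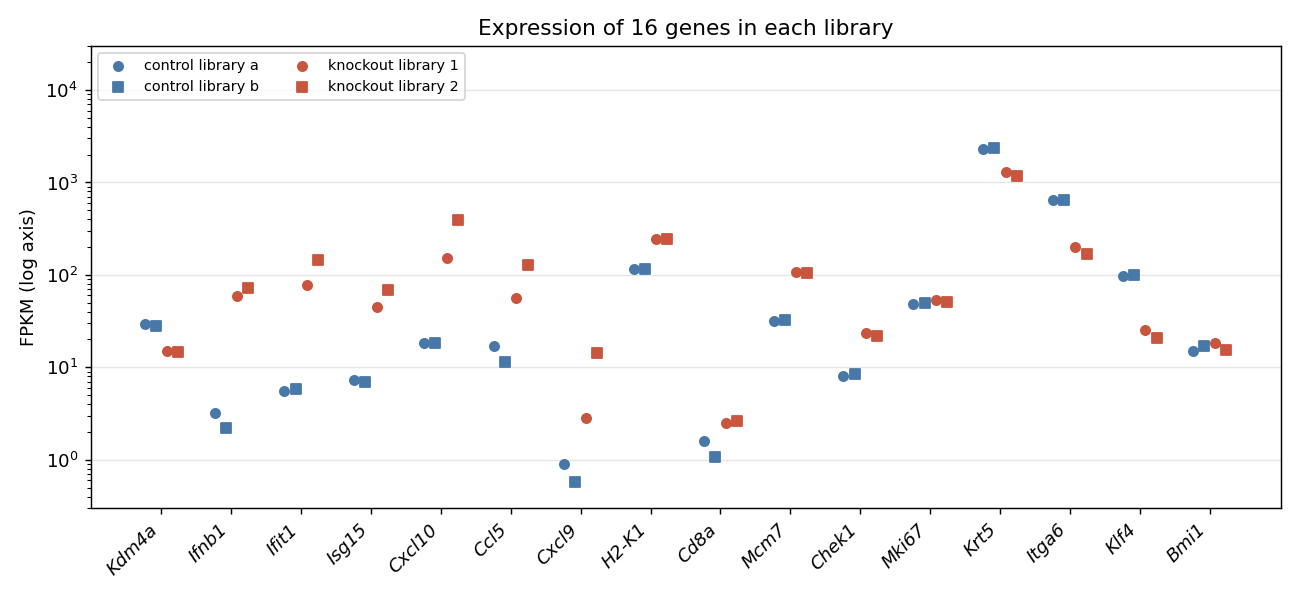
FPKM of 16 genes in each of the 4 libraries on a log axis, with control libraries in blue and knockout libraries in red, circles for control a and knockout 1 and squares for control b and knockout 2. Ifit1 lies at 5.60 and 5.78 FPKM in control and at 77.1 and 146 in knockout, while Mki67 lies between 48.8 and 54.1 in all 4.

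Interferon-stimulated genes were higher in knockout. Of 40 tested members 37 rose and 0 fell (38 and 0 adjusted over the list alone), with a median log2 fold change of 1.82 (camera adjusted p = 3.6e-09). The call was lost with an estimated correlation (adjusted p = 0.715) and with fry (adjusted p = 0.0576). None of the 32 lists passed camera with an estimated correlation (smallest adjusted p = 0.715), so that loss is not particular to any list. Ifit1, whose product binds viral RNA, rose from 5.69 ± 0.13 to 112 ± 48.7 FPKM, and the ubiquitin-like modifier Isg15 from 7.12 ± 0.15 to 56.7 ± 16.8 FPKM (SD, n = 2). The antiviral GTPase gene Mx2 rose by 3.01 on the log2 scale (SE 0.17, adjusted p = 0.000415). The list was higher in knockout library 2 than in library 1 by a median of 0.81 on the log2 scale, markers of B and plasma cells by 0.70, dendritic cells by 0.51, neutrophils by 0.28, macrophages by 0.27, cytotoxic cells by 0.08 and T cells by 0.06.

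Chemokines that attract T cells rose in 10 of 13 tested members, and 1 fell (the same counts adjusted over the list alone; median 2.14, camera adjusted p = 0.000841, adjusted p = 0.715 with an estimated correlation). Ccl4 and Ccl3, which encode chemokines of macrophages and T cells, rose: Ccl4 from 10.7 ± 3.31 to 254 ± 65.3 FPKM and Ccl3 from 4.68 ± 1.33 to 84.6 ± 14.4 FPKM (SD, n = 2). Ccl2 was 4.49 times as high. Cxcl10 stood at 18.4 and 18.4 FPKM in control and at 153 and 391 in knockout (log2 fold change 3.66, SE 0.43, adjusted p = 0.00196), 2.98 without knockout library 2 and 4.34 without library 1. Ccl5 rose by 2.51 (adjusted p = 0.00541), and by 1.92 or 3.10 without 1 knockout library. Cxcl9 rose by 2.14 (adjusted p = 0.0372), and by 3.14 without knockout library 1 and 1.13 without library 2. That call was lost without control library a (adjusted p = 0.0515) or b (0.0741), with a pseudocount of 5 (0.0697), with no filter (0.0587) and with robust eBayes (0.143). Cxcl11 lay at 0.061 and 0.172 FPKM in control and 0.50 and 2.59 in knockout, below the level tested. The member that fell, Ccl20, was noted after its values were seen (-0.53, adjusted p = 0.0266), and its call was lost without control library b or either knockout library (adjusted p = 0.148, 0.0868 and 0.0589).

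In the list of nucleic acid sensing and interferon induction, 13 of 19 members rose and 2 fell (the same adjusted over the list alone). Its median was 0.95 (camera adjusted p = 0.00416). The list call was lost with an estimated correlation (adjusted p = 0.715) and with fry (adjusted p = 0.0621). The list is mixed: it also holds Ifnb1 and Samhd1, and shares Ddx58, Ifih1 and Zbp1 with the interferon-stimulated genes. Of the 4 members not called, the sensor gene Mb21d1 was chosen after its values were seen (0.0036, limma adjusted p = 0.983). Ifnb1, which encodes interferon beta, rose from 2.71 ± 0.745 to 65.9 ± 9.90 FPKM (SD, n = 2; log2 fold change 4.18, SE 0.18, adjusted p = 0.000297). Samhd1, a dNTP hydrolase that restricts nucleic acid accumulation, rose from 12.1 ± 0.394 to 61.2 ± 4.95 FPKM. The members that fell, named after their values were seen, were the adaptor gene Mavs (-0.70) and the transcription factor gene Irf3 (-0.58); the call on Irf3 was lost without control library a or b (adjusted p = 0.0556 and 0.0881) and with quantile normalization (0.0506).

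Class I antigen processing and presentation genes rose in 13 of 19 members and none fell (median 0.76, camera adjusted p = 5.66e-05, adjusted p = 0.715 with an estimated correlation; the same counts adjusted over the list alone). The peptide-loading gene Tapbp rose from 19.1 ± 0.27 to 60.8 ± 4.12 FPKM and the class I heavy chain gene H2-K1 from 116 ± 1.74 to 246 ± 0.13 FPKM (SD, n = 2). Immune checkpoint ligands and receptors rose in 11 of 14 members, and none fell (11 and 1 adjusted over the list alone; median 0.80, camera adjusted p = 0.00444, adjusted p = 0.715 with an estimated correlation). Lgals9, which encodes galectin-9, rose by 1.11 and the inhibitory receptor gene Lag3 by 0.87. Cd274, which encodes the PD1 ligand PD-L1 and was chosen after its values were seen, rose from 2.32 ± 0.38 to 15.4 ± 6.85 FPKM (log2 fold change 2.24, SE 0.30, adjusted p = 0.00287).

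Markers of lymphocytes and macrophages were higher in knockout. T cell markers rose in 18 of 19 members (18 adjusted over the list alone; median 0.85, camera adjusted p = 5.91e-05), B and plasma cell markers in 10 of 14 with 1 fall (11 and 1; median 1.03, adjusted p = 0.0107) and macrophage and monocyte markers in 12 of 21 (15; median 0.42, adjusted p = 0.00387). These 3 calls were lost with an estimated correlation (adjusted p = 0.715 for each), the B cell call with a filter of 5 FPKM (adjusted p = 0.322), and the B cell and macrophage calls with fry (adjusted p = 0.116 for each). The T cell adaptor gene Lat rose from 2.61 ± 0.26 to 7.86 ± 0.30 FPKM and the complement receptor gene Cr2 from 0.579 ± 0.0855 to 2.31 ± 0.541. Sdc1, a marker of plasma cells that epithelial cells also express, fell by 0.63. Cd8a rose by 0.62 (adjusted p = 0.0179), a call lost without control library b (adjusted p = 0.0979) or knockout library 1 (0.053) or 2 (0.069). The T cell adhesion gene Cd2 rose by 1.30, the macrophage marker Cd68 by 0.78 and Apoe, a lipid carrier made by macrophages, by 0.57. Cytotoxic T and NK cell markers (5 of 6 rose, median 0.67), dendritic and Langerhans cell markers (7 of 9 rose, 1 fell, median 0.72) and neutrophil markers (5 of 10 rose, 1 fell, median 0.41) did not pass as lists (camera adjusted p = 0.0954, 0.0606 and 0.127). Nkg7, a gene of cytotoxic granules, rose by 0.66 (adjusted p = 0.0503 without control library b). The class II regulator gene Ciita rose by 0.94 (0.0522 without control library b) and the actin-bundling gene Fscn1 by 0.27 (0.153 without control library a and 0.0716 without b). In the neutrophil list S100a8 rose by 0.61 and the receptor gene Cxcr2 fell by 0.99. S100a8, Fscn1 and Epcam had control means of 100, 157 and 234 FPKM, and RNA of whole tumours does not show which cells made them. Epcam, which fell in the dendritic list, was named after its values were seen (-0.22; adjusted p = 0.124 without control library a, 0.262 without b, 0.0509 without knockout library 2 and 0.0682 by eBayes without a trend). The dendritic list passed without control library a (adjusted p = 0.0201) or knockout library 1 (0.0186) and with short genes left out (0.0498), the cytotoxic list without control library a (0.0317), with no filter (0.0297) or with fry (0.0457), and the neutrophil list without knockout library 1 (0.0399) or with no filter (0.0333).

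Salivary gland and secretory epithelium markers rose in 8 of 10 members and 1 fell (the same adjusted over the list alone; median 1.58, camera adjusted p = 0.0142, adjusted p = 0.715 with an estimated correlation). After the trend with gene length was removed the adjusted p was 0.0709 and the median 1.40. Knockout library 2 differed from library 1 by a median of -0.69 on the log2 scale over the list. Of its 10 members 5 were lower in library 2, the secretory genes Amy1, Bpifa2, Dcpp1, Dcpp3 and Pip, and the other 5 were not. Fibroblast markers rose in 2 of 12 (Thy1 and Sparc), endothelial markers rose in 2 of 7 and fell in 1, skeletal muscle markers rose in 1 of 21 (Eno3) and adipocyte markers fell in 1 of 8 (Fabp4), with medians of 0.12, 0.21, 0.11 and -0.18 and camera adjusted p of 0.325, 0.364, 0.18 and 0.657. The vascular gene Egfl7 rose by 0.70 and the receptor gene Flt1 fell by 0.75, a change of 0.03 after the length trend was removed. Pecam1 and the salivary list member Krt18 were named after their values were seen. Pecam1 rose by 0.52 (adjusted p = 0.222 without control library b, 0.0517 without knockout library 1, 0.146 without library 2 and 0.0615 with no filter), and Krt18 fell by 0.31 (0.103 without control library a and 0.0834 without b). Pvalb of the muscle list stood at 0.37 (adjusted p = 0.0535; 0.0358 to 0.0498 with a pseudocount of 5, median-ratio scaling, eBayes without a trend or short genes left out) and Cfd of the adipocyte list at -1.02 (0.0959; -1.61 with 0.00883 without control library a, and -0.43 with 0.286 without b). The muscle list passed without knockout library 1 (median 0.27, adjusted p = 0.00361), and the call on Fabp4 was lost without control library a or b (adjusted p = 0.0746 for each), with quantile normalization (0.0586) and after the length trend was removed (0.0759).

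**Figure D2:**
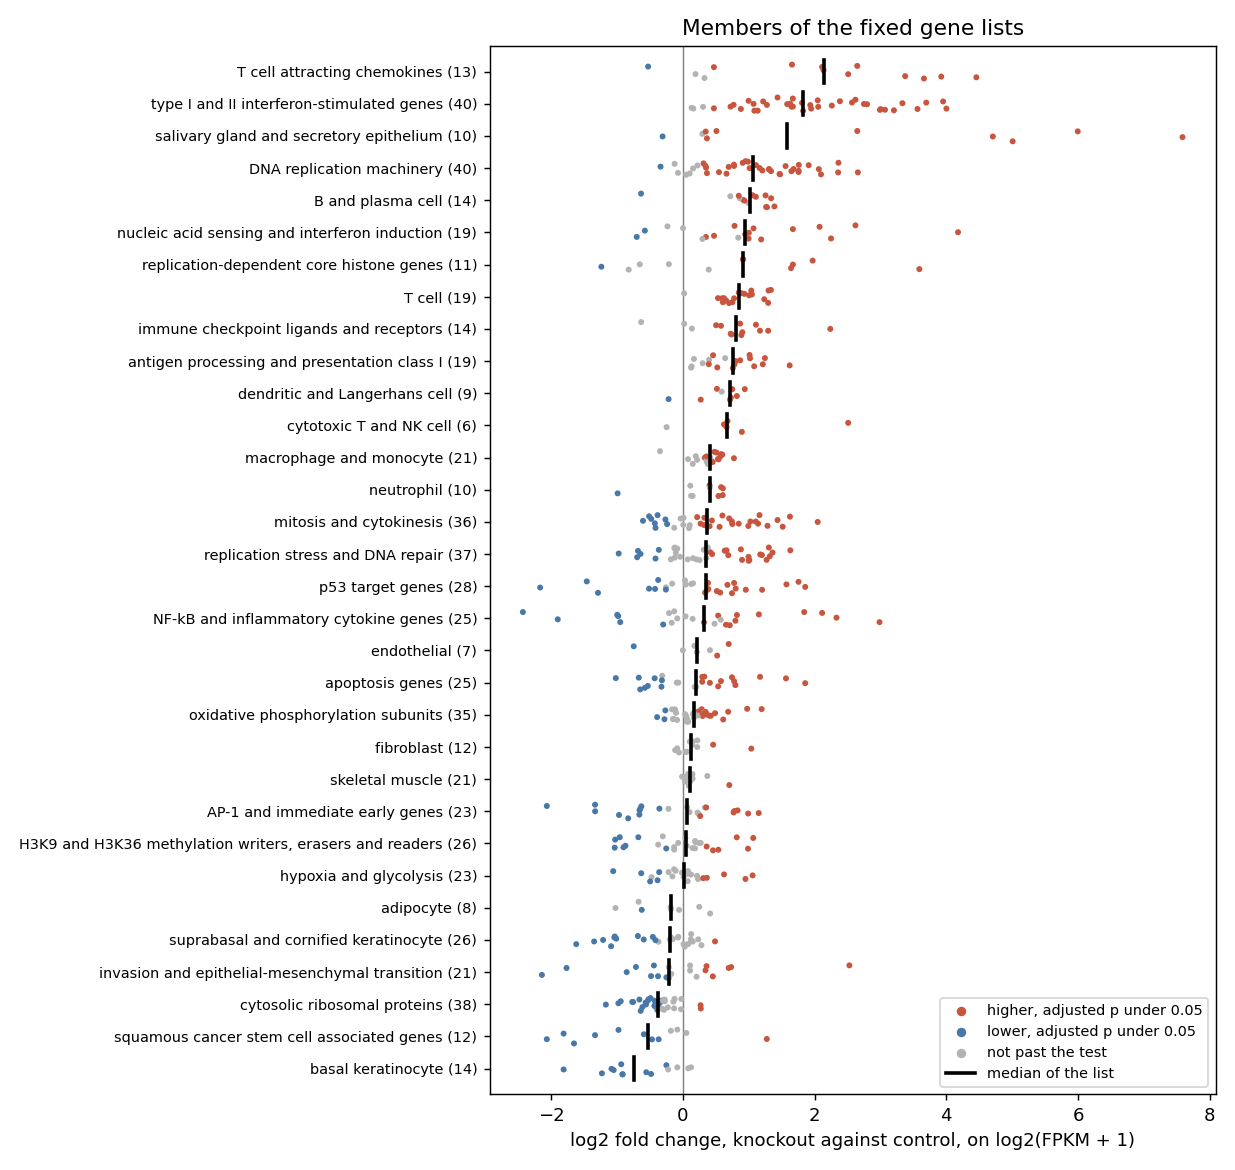
Log2 fold change of each tested member of the 32 gene lists, knockout against control on log2(FPKM + 1), with the number of members in parentheses, red for called rises, blue for called falls, grey for members not past the test and a black bar at the list's median. Medians run from -0.73 in basal keratinocyte markers to 2.14 in chemokines that attract T cells.

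Genes of the DNA replication machinery were higher in knockout. Of 40 members 33 rose and 1 fell (the same adjusted over the list alone), with a median log2 fold change of 1.06 (camera adjusted p = 5e-10, adjusted p = 0.715 with an estimated correlation). The helicase subunit gene Mcm7 rose from 32.1 ± 0.54 to 105 ± 1.91 FPKM and the helicase cofactor gene Cdc45 from 12.3 ± 0.29 to 49.0 ± 1.21 (SD, n = 2). Pola1, the member that fell, was named after its values were seen (-0.34, adjusted p = 0.0413); it lost the call without control library a or b or knockout library 2 (adjusted p = 0.133, 0.307 and 0.0824), with no filter (0.0548) and with quantile normalization (0.122), and was higher in knockout after the length trend was removed (0.38, adjusted p = 0.021). Mitosis genes rose in 22 of 36 members and fell in 8 (the same adjusted over the list alone; median 0.37, camera adjusted p = 0.00207), and genes of replication stress and DNA repair rose in 17 of 37 and fell in 6 (the same adjusted over the list alone; median 0.36, adjusted p = 0.0123; 22 and 8 after the length trend was removed). Both calls were lost with an estimated correlation (adjusted p = 0.715 for each). Spc25 and Kif20a, of the kinetochore and the mitotic spindle, rose by 2.05 and 1.44, the checkpoint kinase gene Chek1 by 1.36 and the recombination gene Rad54l by 1.63. The proliferation marker Mki67 differed by 0.09 (adjusted p = 0.263) and, after the length trend was removed, by 0.91 (adjusted p = 0.000421).

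Targets of p53 rose in 15 of 28 members and fell in 7 (the same adjusted over the list alone), and the list did not pass (median 0.35, camera adjusted p = 0.0937, 0.0322 with fry). Gadd45b rose by 1.57 and the stress-response gene Sesn2 fell by 2.17. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 31.6 ± 2.15 to 47.5 ± 7.80 FPKM (SD, n = 2; log2 fold change 0.57, adjusted p = 0.0146), a call lost without control library a (adjusted p = 0.0577). Replication-dependent core histone genes rose in 6 of 11 members and fell in 1 (median 0.91, camera adjusted p = 0.18). Hist1h4i stood at 3.59 and Hist1h2bc at -1.24. Polyadenylated RNA was selected, so these values need not reflect the total RNA of histone genes. Apoptosis genes rose in 12 of 25 and fell in 8 (median 0.20, adjusted p = 0.361, 0.0287 with fry); Pmaip1, which encodes NOXA, rose by 1.86.

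Basal keratinocyte markers were lower in knockout. Of 14 members 10 fell and none rose (the same adjusted over the list alone), with a median of -0.73 (camera adjusted p = 0.00416, adjusted p = 0.715 with an estimated correlation). Krt5 fell from 2336 ± 48.7 to 1237 ± 68.7 FPKM and Krt14 from 2247 ± 17.1 to 1530 ± 55.7 (SD, n = 2). The integrin subunit genes Itga6 and Itgb4, which anchor basal cells to the basement membrane, fell by 1.81 and 1.08. Trp63, a basal lineage transcription factor, differed by -0.08 (adjusted p = 0.528); the difference was -0.22 without knockout library 1 (adjusted p = 0.0337) and 0.48 after the length trend was removed (adjusted p = 0.00506). Suprabasal markers fell in 11 of 26 and rose in 1 (10 and 1 adjusted over the list alone; median -0.19, camera adjusted p = 0.0773), with Dsc2 at -1.62 and Krt17 at -1.01. Sprr1b, the member that rose, was named after its values were seen (0.49; adjusted p = 0.0949 without control library b). That list passed without control library a (adjusted p = 0.0447), without knockout library 2 (0.00829) and after the length trend was removed (0.022).

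Genes associated with squamous cancer stem cells fell in 8 of 12 members and rose in 1 (the same adjusted over the list alone; median -0.53, camera adjusted p = 0.0247, adjusted p = 0.715 with an estimated correlation). Itga6 belongs to this list and to the basal one. Klf4, a transcription factor of differentiation and pluripotency, stood at 97.7 and 101 FPKM in control and at 25.4 and 20.7 in knockout (log2 fold change -2.06, adjusted p = 0.000394). The member that rose was Ezh2 (1.27), a histone methyltransferase gene named after its values were seen. Bmi1 differed by 0.05 (adjusted p = 0.711). Genes of invasion and epithelial-mesenchymal transition (6 rose and 8 fell of 21, median -0.21) and AP-1 and immediate early genes (7 rose and 10 fell of 23) did not pass (camera adjusted p = 0.454 and 0.761, 0.0322 and 0.0392 with fry). In the AP-1 list the median was 0.07 while the mean was -0.16 and camera gave a negative direction. The matrix gene Tnc fell by 2.14, Tgfb1 fell by 0.85 and Egr1 rose by 1.15. Inflammatory NF-kB genes rose in 11 of 25 and fell in 6 (median 0.32, adjusted p = 0.275), with the prostaglandin synthase gene Ptgs2 rising from 84.9 ± 0.74 to 307 ± 3.69 FPKM.

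Cytosolic ribosomal protein genes fell in 25 of 38 members and rose in 2 (27 and 2 adjusted over the list alone; median -0.38, camera adjusted p = 0.000343, adjusted p = 0.715 with an estimated correlation and 0.0978 with fry). Rpl3 fell by 1.17 and Rpl6 by 0.94. The members that rose, named after their values were seen, were Rps19 and Rplp0 (0.27 for each); without control library a their adjusted p were 0.227 and 0.37, without b 0.151 and 0.251, and without knockout library 2 0.0535 and 0.0832. The call on Rps19 was also lost by eBayes without a trend (0.0559), and that on Rplp0 with a pseudocount of 5 (0.0508), no filter (0.0645), a filter of 5 FPKM (0.0581) and the length trend removed (0.167). With that trend removed, 32 members of the list fell and 1 rose. Oxidative phosphorylation subunits rose in 15 of 35 and fell in 3 (14 and 2; median 0.17, camera adjusted p = 0.0275, adjusted p = 0.715 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.361), without control library a (0.0675), without knockout library 2 (0.0616) and after the length trend was removed (0.874), when 9 members rose, 9 fell and the direction of the test turned. Ndufs3 rose by 1.20 and Atp5b by 0.98. Named after their values were seen, Ndufa4, Atp5c1 and Cox7c fell by 0.27, 0.28 and 0.39. Without control library a their adjusted p were 0.146, 0.0903 and 0.0551; without b those of Ndufa4 and Atp5c1 were 0.224 and 0.104, and that of Ndufa4 was 0.0637 without knockout library 1, 0.0599 with no filter, 0.0564 with median-ratio scaling and 0.0707 by eBayes without a trend. Writers, erasers and readers of H3K9 and H3K36 methylation rose in 6 of 26 and fell in 7 (median 0.05, mean -0.05, adjusted p = 0.761). After the length trend was removed 12 rose and 2 fell (median 0.22, adjusted p = 0.0617). The H3K9 methyltransferase gene Suv39h1 rose by 0.99 and the H3K36 methyltransferase gene Nsd1 fell by 1.03, a change that was -0.02 after the length trend was removed (adjusted p = 0.845). Hypoxia and glycolysis genes rose in 5 of 23 and fell in 5 (median 0.01, adjusted p = 0.707), with Hk2 at -1.06 and Tpi1 at 0.95.

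Fold changes fell with gene length. Across 11958 genes, which are not independent replicates, the rank correlation of the log2 fold change with the length of the longest transcript was -0.26, and with the genomic span -0.21. Between the knockout libraries the difference of library 2 from library 1 had a rank correlation with transcript length of -0.27, and the difference between the control libraries of -0.08. The median log2 fold change was 0.19 in the tenth of genes with the shortest transcripts and -0.43 in the tenth with the longest. After the trend was removed, 82.7% of the called genes were still called in the same direction and 184 in the opposite one. Genes higher in knockout made up 54.7% of the calls then, against 47.1% before, so that the excess of lower genes became an excess of higher ones.

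**Figure D3:**
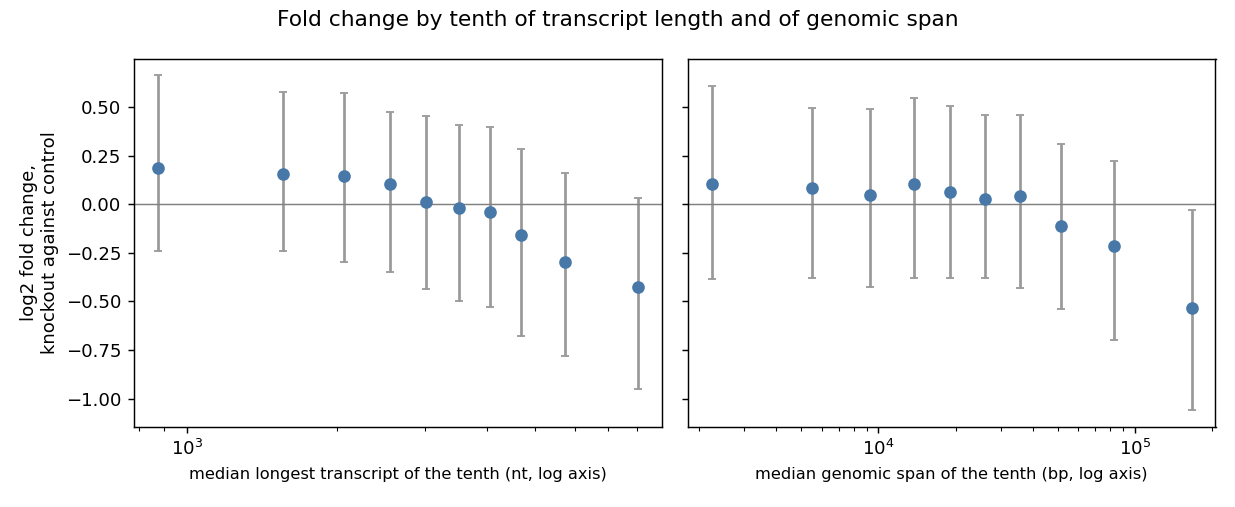
Median log2 fold change, knockout against control, in groups of equal size of the tested genes by longest transcript (left) and genomic span (right), each plotted at the median length of the group on a log axis; bars run from the 25th to the 75th percentile of the genes. The median falls from 0.19 to -0.43 with transcript length, and lies at -0.53 in the tenth with the longest genomic span.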

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

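The removal of the length trend and the omission of short genes were chosen after the data were seen; the other alternatives were planned. Among 138 named genes, 101 kept their direction and their side of the threshold under each alternative to the values or the fit in which they were tested (123 were tested with the filter of 5 FPKM), and 22 of 32 gene lists (27 with that filter) did so, by the direction of the test, apart from the estimated correlation and fry. Of the 132 named genes called, 89 changed by at least 1 on the log2 scale and the others, Kdm4a among them, would lose the call under that limit; of the 6 not called, Pvalb and Cfd would gain it at an adjusted p of 0.1. Kdm4a ranged from -0.95 to -0.76, with adjusted p of at most 0.00754. Of the 3628 genes higher and 4073 lower, 822 and 1228 changed by at least 1 on the log2 scale; without control library a or b 44.6% and 43.5% of the genes were called, and without knockout library 1 or 2 67.6% and 64.4%. With an estimated correlation 0 lists were higher and 0 lower, against 13 and 3 with the preset value. The salivary list lost its call too, though its estimated correlation was -0.087, below the preset 0.01. That form rests on 2 residual degrees of freedom, so a call lost there does not show correlation among a list's genes. Medians do not depend on that choice: 1.82 for interferon-stimulated genes, 2.14 for chemokines, 1.06 for DNA replication and 0.85 for T cell markers. Each of these lists then had camera adjusted p = 0.715. Fry gave an adjusted p of 0.0576 for the interferon-stimulated genes, again at a median of 1.82.

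After the length trend was removed, values on the other side of 0 or in the other direction were -0.053 for hypoxia genes, 0.067 for oxidative phosphorylation (where the test turned and the median did not), 0.047 for invasion genes (where the median turned and the test did not), 0.026 for Flt1, 0.48 for Trp63 and 0.38 for Pola1; the cause was not tested. With a filter of 5 FPKM the medians of H3K9 and H3K36 genes and of AP-1 genes were -0.016 and -0.22, and with quantile normalization that of AP-1 genes was -0.027. Without 1 library, ranges that crossed 0 were -0.047 to 0.16 for H3K9 and H3K36 genes, -0.12 to 0.13 for hypoxia genes, -0.045 to 0.27 for muscle markers, -0.05 to 0.064 for AP-1 genes, -0.067 to 0.17 for Bmi1, -0.22 to 0.057 for Trp63 and -0.029 to 0.15 for Kdm4b. Removing a library leaves 1 in its group, assumed to vary like the other group. No paired analysis was possible because both control columns carry the same name. The planned edgeR and DESeq2 tests were not run, since they need counts.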

Other observations

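The gene lists of this paragraph and the next, Ifna4, the comparison of short genes with longer ones, and the tests on the longest genomic spans, T cell against muscle markers, B cell against salivary genes, interferon-stimulated genes against immune markers and Hspa1b were chosen after the data were seen. Genes of cholesterol synthesis rose in 22 of 24 members and 1 fell (the same adjusted over the list alone; median log2 fold change 1.04, camera adjusted p = 6.25e-08, adjusted p = 0.317 with an estimated correlation). Acat2, which makes acetoacetyl-CoA, stood at 6.47 and 7.45 FPKM in control and at 90.7 and 65.3 in knockout, and the mevalonate pathway gene Mvd rose from 9.38 ± 0.467 to 86.9 ± 16.8 FPKM (SD, n = 2). The squalene synthase gene Fdft1 rose by 2.53 and the isomerase gene Idi1 by 2.23. The regulator gene Srebf2 fell by 0.51, a call lost without control library a or b (adjusted p = 0.0637 and 0.0659) and after the length trend was removed (0.0622). Heat shock protein genes rose in 16 of 20 and fell in 2 (the same adjusted over the list alone; median 0.92, adjusted p = 2.41e-05, adjusted p = 0.105 with an estimated correlation). The chaperone gene Hspa8 rose by 2.10 and its cochaperone gene Dnajb1 by 2.29, while Hspa4 fell by 1.15 and the mitochondrial Hspa9 by 1.32.

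Genes of the proteasome regulatory particle rose in 13 of 17 members and none fell (the same adjusted over the list alone; median 0.48, adjusted p = 5.9e-06, adjusted p = 0.105 with an estimated correlation), with the ATPase gene Psmc5 at 1.49 and the lid gene Psmd6 at 1.32. Circadian clock and output genes fell in 11 of 16 and rose in 3 (the same adjusted over the list alone; median -0.84, adjusted p = 0.00905, adjusted p = 0.377 with an estimated correlation): the output gene Dbp fell from 41.8 ± 5.40 to 4.75 ± 0.185 FPKM and the repressor gene Nr1d1 from 313 ± 5.67 to 104 ± 5.97 (SD, n = 2). Per2 fell by 1.39. Ciart rose by 1.02, Nfil3 by 0.51 (adjusted p = 0.0567 without control library b) and Bhlhe40 by 0.34 (0.0621 to 0.333 without any 1 of the libraries, 0.0501 with a pseudocount of 0.1 and 0.0645 with no filter). Ifna4, an interferon alpha gene with near-identical relatives, stood at 0.31 and 0.14 FPKM in control and at 10.3 and 12.8 in knockout. Among 171 tested genes with transcripts under 300 nt, 22 had called changes of at least 5 on the log2 scale, against 7 of 11787 longer genes, and 97 were listed at 0 in at least 1 library.

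Genes with long transcripts were lower in knockout. The partial rank correlation of the fold change with transcript length, given genomic span, was -0.176 across 11958 genes, and with span, given transcript length, -0.0507, which argues against span along its whole range. In the 1196 genes with the longest spans the median differed by -0.36 from that of genes of like transcript length. The permutation over genes gave p = 0.001, the smallest that 1000 resamples can give. Genes are not independent replicates, so that p does not measure spread between samples. Lower levels of very long genes may add to a length bias of the libraries. The trend is unlikely to be the whole cause of the gene calls, since 82.7% were called in the same direction after its removal. A length bias and an effect of the knockout on long genes could not be separated, as either would follow the groups in this design, and knockout library 2 differed from library 1 in the same sense (partial rank correlation -0.153).

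Lymphocyte and salivary gland markers were higher in knockout. A lower share of keratinocytes raises other cell types alike, yet T cell markers (median 0.85) rose more than muscle markers (0.11, permutation p = 2e-05). That p, like the next, runs over marker genes, which are not independent replicates. It does not measure spread between samples, so it cannot exclude a lower keratinocyte share. A single adjacent tissue piece in a fixed mixture would move both sets together between the knockout libraries. Library 2 differed from library 1 by a median of 0.70 on the log2 scale over the 14 B cell markers and of -0.69 over the 10 salivary markers (permutation p = 0.00026). Of these 10, the secretory genes Amy1, Bpifa2, Dcpp1, Dcpp3 and Pip were lower in library 2 and the other 5 were not, and each library is 1 sample, so a fixed mixture could not be excluded. Salivary gland tissue may be a source of the secretory genes, and whether the lymphocytes lay in the tumour or beside it stays open.

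Interferon-stimulated genes had a median log2 ratio of 2.44, against medians of 0.45 to 1.57 in 6 immune marker lists. The largest permutation p against these was 0.0657, for 5 cytotoxic cell markers, and the next 0.047, for B cell markers. These permutations run over genes, which are not independent replicates. More immune cells at an unchanged interferon state therefore could not be excluded. An earlier form of this test, against the highest single marker, left out the cytotoxic list. There Pax5 was highest (log2 ratio 2.10), below the median of the interferon-stimulated genes. With all 6 lists Ccl5 was highest (2.68), above that median and exceeded by 17 of 40, so that form does not exclude more immune cells either. Ccl5 is also in the chemokine list, so it is not a marker of cytotoxic cells alone. The length trend is unlikely as a cause. On the log2(FPKM + 1) scale the median was 1.82 before its removal and 1.79 after (camera adjusted p = 9.19e-07). The 2.44 above is instead a log2 ratio of FPKM means. Stress in handling cannot be told apart from an effect of the knockout: Hspa1b, a heat-inducible gene near-identical to Hspa1a, rose by 4.45 (7.74 and 9.62 FPKM in control, 195 and 224 in knockout), and the labels record no handling times. An effect of the Kdm4a knockout stays open for this pattern and the other patterns here.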
